A study of Gallus gallus with 6 samples.

How the data were processed

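RNA was sequenced from the cochlear duct of chicken embryos at embryonic day 6.5. Per the labels' protocols, ducts were cut into 3 pieces of similar length (proximal, middle and distal), and the pieces of each region were combined across ducts before RNA extraction. Polyadenylated RNA was captured on oligo-dT beads, fragmented and copied with random primers, per the same protocols, and libraries were sequenced on an Illumina instrument. The protocols name alternative Illumina library kits, and which kit served which library is not given in the sources used here. They also state that separate biological replicates were prepared. The 6 libraries comprise 2 per region. The number of ducts or embryos in each pool is not given in the sources used here.

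The measurements are RPKM values per gene (reads scaled by gene length and by the number of aligned reads), as deposited by the authors. Per the submitters' processing notes, TopHat 1.4.0 and Partek 6.6 were used. The genome build, the annotation and any use of strand in counting are not given in the sources used here, so positions of genes are not printed. The column names of the authors' RPKM table tie each library to its region and to either a first or a second set, so that every region has 1 library in each of 2 sets. They do not tie a library to an individual sample record. The table also carries the number of alignments of each library. That entry is not a gene and was kept out of all sums and tests. Whole reads were not recovered from the RPKM values. In 69.7% of 238 genes with low values, all values above 0, once multiplied by the library totals, were whole multiples of a common step within a tolerance of 0.05. The mean was 0.2% of genes when the library totals were perturbed. The low values thus carried steps of whole reads, but read counts were not rebuilt from them, and the count models were not used.

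The table names 17684 genes. Of these, 12629 carry a gene symbol, and 11536 of the symbols occur in the RefSeq gene table of assembly GRCg7b, which was used for names only. A further 4080 entries carry Ensembl identifiers, of which 0 matched that table, and 198 of 499 locus names matched. Another 456 entries have protein-style names, and 20 have names that look like calendar dates, as spreadsheets make of gene symbols. Entries without a symbol were tested, and 2182 of the 12559 genes tested have none. They are counted below but not named.

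Each value was transformed to log2(RPKM + 1), with a pseudocount of 1, which understates the change of genes with low values. A gene was tested if it reached 1 RPKM in at least 2 of the 6 libraries. Linear models were fitted with limma 3.58.1 in R 4.3.3, with region as a factor over all 6 libraries, empirical Bayes moderation with a trend, two-sided tests and Benjamini-Hochberg adjustment. The threshold was an adjusted p below 0.05. A moderated F test asked whether a gene differed between any regions. This model without a set term, called the unblocked model, was fixed before the data were examined, as were the named genes' rule, the 28 gene lists and most alternatives.

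A second fit, also fixed beforehand, added the library set as an additive term, called the replicate block or the blocked model. Whether the sets pair the libraries was decided before the calls were compared. Across genes, the difference between the sets correlated between proximal and middle at 0.659, between proximal and distal at 0.655 and between middle and distal at 0.885, all above the minimum of 0.1, and the pairing itself comes from the column names. The unblocked model has 3 residual degrees of freedom and the blocked model 2. For counts over all genes and for list calls the blocked value stands beside each result it changes. The SE and adjusted p of single genes, and the members counted over a list alone, are from the blocked model. The unblocked SE could be much larger. For FGFR3 between distal and proximal it was 0.70 unblocked and 0.20 blocked.

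The 28 gene lists cover signalling pathways, patterning factors, cell types of the ear, other cell types that the pieces could hold, and signs of proliferation, handling stress and metabolism. They were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. Members of a list were also counted with p-values adjusted over the list alone. Lists with at least 5 tested genes were used.

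Genes were named by a rule. For distal against proximal, 12 genes per direction were taken, and for the other pairs of regions 6 per direction. Genes past the threshold were to be ranked by fold change. Because the unblocked model called 0 genes, places were filled by the smallest unblocked p among genes whose libraries did not overlap between the regions and whose log2 change was at least 1 in size. Up to 4 members of each list with the smallest p, and all tested members of the BMP ligand, BMP antagonist and retinoic acid lists, were added. Genes chosen after their values were seen are marked as such.

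The models were tested on simulated data of 12559 genes, in which 200 genes were changed between distal and proximal. The simulation used the residual spread of the blocked model and gave each gene the same set difference in all regions, as that model assumes. In the real libraries the set difference correlated between regions at 0.655 to 0.885, so the simulated rates may not carry over to them. The unblocked model recovered 0% of the changed genes at a log2 change of 1 or 2, 30.3% at 3 and 80.5% at 4, with a mean of 0 false calls. The blocked model recovered 7.7%, 98.9%, 100% and 100% at these sizes, with a mean of 5.2, 17.8, 14.6 and 17.2 false calls, and made a mean of 1.8 calls when no gene was changed. A neuron list lowered by 0.7 was found in 10 of 10 simulations with either model. The simulated genes varied independently of each other, so this does not show how the list test behaves where genes of a list vary together.

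Alternatives were a pseudocount of 0.1, no filter on low values, a mean RPKM of at least 5, quantile normalization, no trend, only the regions compared, position along the duct as a linear term, the replicate block, and leaving out each library in turn. Combinations of the block with these, and array weights, were added after the data were seen. Plots were drawn with matplotlib 3.10.9.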

Results

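Gene expression along the cochlear duct of the chicken was measured at embryonic day 6.5, before the hair cells of the auditory epithelium mature. The duct holds the future basilar papilla, the hearing organ of birds, in which high frequencies are sensed near the proximal end and low frequencies near the distal end. It also holds the future tegmentum vasculosum, a secretory epithelium facing the papilla. The distal piece further contained the prospective lagena, a macular organ at the tip of the duct. The comparisons asked which genes differ between the proximal, middle and distal pieces, with 2 libraries (a first and a second set) per region. The first set held 14489623 alignments in the proximal, 23537713 in the middle and 9262860 in the distal library, and the second set 73918748, 66072315 and 56103107. One read per kilobase of gene was thus worth between 0.0135 RPKM (proximal, second set) and 0.108 RPKM (distal, first set).

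The sets differed more than the regions did. The first principal component held 63.4% of the variance and separated the sets, and the second held 24.3%. Within the first set the proximal library stood apart on the first component (-66.5, against -35.7 for the middle and -33.7 for the distal library). Across genes, log2 values correlated at 0.918 to 0.984 between regions of the same set, and at 0.888 (proximal), 0.928 (middle) and 0.924 (distal) between the sets of the same region. Genes are not independent replicates in these correlations. Ribosomal protein genes held 21.5% to 25.3% of the summed RPKM in the first set and 13.4% to 15.4% in the second, and mitochondrial genes 4.26% to 6.47% and 7.06% to 7.57%. At 1 RPKM or more, 11315 to 11666 genes were detected in the first set and 12215 to 12281 in the second. Changes below are given as log2 change ± SE on the log2(RPKM + 1) scale, with the SE from the model with the set as a replicate block. Members counted as adjusted over the list alone are also from that model, and camera values from the unblocked one unless stated. Without the block these member counts were lower or equal between distal and proximal. Neuron genes had 5 lower against 16 with the block, and Wnt genes 2 higher and 1 lower against 14 and 5. Glycolysis and hypoxia genes had 1 higher against 8, and FGF genes 0 against 4. Levels are given as mean RPKM ± SD of n = 2 libraries.

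CYP26C1 and APOA1 were higher and OTOL1 and NEUROD1 lower in the distal than in the proximal piece. CYP26C1, an enzyme that breaks down retinoic acid, measured 42.4 ± 1.19 RPKM in the distal and 2.74 ± 0.101 in the proximal piece, a log2 change of 3.54 ± 0.22. APOA1, the main protein of high-density lipoprotein, measured 110 ± 53.6 against 3.17 ± 0.401, a change of 4.64 ± 0.27. In the other direction, OTOL1, which encodes the otoconial matrix protein otolin, measured 0.568 ± 0.270 RPKM in the distal and 33.3 ± 14.0 in the proximal piece, a change of -4.40 ± 0.25. The neuronal transcription factor gene NEUROD1 measured 5.79 ± 0.628 against 57.9 ± 32.7, a change of -3.0 ± 0.30. Each of these genes passed the threshold in the blocked limma model, with adjusted p = 0.0145, 0.0145, 0.0145 and 0.0355.

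In limma, 66 genes passed with the replicate block, 31 higher and 35 lower in the distal piece, 7 of them without a symbol, and 1847 genes had an unadjusted p under 0.05. In the simulations false calls made up more than 0.05 of the blocked calls, so blocked adjusted p may be too small. Without the block, limma called 0 of 12559 genes (508 at an unadjusted p under 0.05), and the smallest adjusted p was 0.194. Within the sets, 146 genes were at least 2-fold higher and 241 at least 2-fold lower in the distal piece in both, where 30.8 and 30.9 would coincide if the sets were independent, and 12 went opposite ways. The first set alone had 1745 higher and 1031 lower at this size, and the second 222 and 376. Over all genes 58.0% had the same sign in both sets. The blocked count ended at 0 without the filter on low values, and under quantile normalization it was 257, with 84 higher and 173 lower. With 1 library left out and 1 value in its region, the blocked count was 800 without the first-set proximal library, 6962 without the second-set proximal, 601 and 597 without the first-set and second-set middle, and 119 and 374 without the first-set and second-set distal.

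Of the 12 genes named as higher in the distal piece, 11 passed with the block. TECTB, which encodes beta-tectorin of the tectorial membrane, reached 29.7 ± 10.6 RPKM against 1.28 ± 0.530, a change of 3.73 ± 0.33. The BMP antagonist NOG rose from 1.27 ± 0.573 to 14.1 ± 2.99 RPKM (2.74 ± 0.29), and the Wnt ligand genes WNT5A and WNT4 by 2.04 ± 0.21 and 1.83 ± 0.20. Also higher were ELF5, an epithelial ETS factor gene (2.44 ± 0.22), OLFM4, which encodes a secreted glycoprotein (2.48 ± 0.23), and ABI3BP, an extracellular matrix gene (2.44 ± 0.22). The proximal level of OLFM4 was 0.0632 ± 0.0192 RPKM, and its first-set value of 0.0497 lay below 1 read per kilobase (0.0690 RPKM in that library). CDH13, an atypical cadherin gene, was higher by 2.70 ± 0.28, and LDHA, which encodes lactate dehydrogenase A, by 2.26 ± 0.19. For these 9 genes the adjusted p with the block lay between 0.0293 and 0.0382. MSX1, a homeobox gene regulated by BMP, missed the threshold in limma (95.3 ± 6.36 against 15.2 ± 10.01 RPKM, 2.72 ± 0.38, blocked adjusted p = 0.0592).

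Of the 12 genes named as lower, 11 passed with the block. OCM2, which encodes a calcium-binding oncomodulin, fell from 33.9 ± 6.37 to 1.54 ± 0.441 RPKM (-3.78 ± 0.25). Reads of near-identical oncomodulin copies cannot be separated here, so its assignment is uncertain. The transcription factor gene ZIC1 fell from 27.2 ± 0.481 to 2.13 ± 0.768 RPKM (-3.19 ± 0.25), and CALB2, which encodes the hair cell and neuron protein calretinin, from 116 ± 79.3 to 10.9 ± 2.13 (-3.12 ± 0.31). Genes used by neurons followed, among them CHGA (chromogranin A, -2.77 ± 0.26), NHLH1 (a neuronal basic helix-loop-helix factor, -2.50 ± 0.30), GAP43 (an axon growth protein, -2.45 ± 0.23), HMP19 (a neuronal vesicle protein, -2.27 ± 0.21) and NRN1 (neuritin, -2.17 ± 0.27). The carboxypeptidase gene CPB1 changed by -2.04 ± 0.22, with a first-set distal value of 0.0870 RPKM, below 1 read per kilobase (0.108 RPKM in that library). Blocked adjusted p for these 9 genes in limma lay between 0.0145 and 0.0468. ALDH1A3, which encodes a retinoic acid synthesizing enzyme, measured 4.01 ± 2.95 against 53.9 ± 23.9 RPKM (-3.52 ± 0.53) and missed the threshold (adjusted p = 0.0698).

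Among BMP ligands, no member passed over all genes. With the block, 2 of 5 tested genes were higher and 1 lower when adjusted over the list alone. BMP7 measured 58.7 ± 34.0 RPKM in the distal and 26.4 ± 13.2 in the proximal piece, a change of 1.09 ± 0.20 (limma, blocked adjusted p = 0.0876), and lay higher in the distal piece in each set. BMP4 measured 41.6 ± 1.91 against 23.8 ± 2.96 (0.79 ± 0.20). GDF3 changed by -0.85 ± 0.28, while BMP5 and BMP2 had values of 0.24 ± 0.22 and 0.31 ± 0.24. BMP2 turned to -0.19 without the first-set proximal library. The ligand list was not called (median 0.31, adjusted p = 0.310).

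The secreted BMP antagonists went both ways. NOG was the 1 member of 7 that passed over all genes with the block, and 2 were higher and 3 lower when adjusted over the list alone. FSTL3, a follistatin relative, had a change of -1.60 ± 0.36, NBL1 of -0.87 ± 0.26 and CHRDL1, a chordin relative, of -0.66 ± 0.23, while BMPER had 0.74 ± 0.21. CHRDL1 measured 20.8 ± 5.51 in the distal and 35.1 ± 17.3 RPKM in the proximal piece. SOSTDC1 and TWSG1 stood at -0.15 ± 0.23 and -0.02 ± 0.20, and the sign of both depended on which library was left out (0.17 and 0.26 without the first-set proximal library, 0.30 and 0.09 without the second-set distal). TWSG1 also had 0.04 under quantile normalization. The list median was -0.15 and its mean 0.03, with no call (adjusted p = 0.672).

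BMP receptors, SMADs and target genes were on balance higher in the distal piece. Of 17 tested genes 14 had a mean change above 0 (median 0.26), but only 7 were higher in both sets and 2 lower in both. Camera gave adjusted p = 0.0462, lost with the block (0.0716) and at adjusted p = 0.475 with an estimated correlation. BAMBI, a BMP-induced pseudoreceptor gene, passed over all genes with the block (125 ± 36.4 against 34.8 ± 6.40 RPKM, 1.80 ± 0.19, limma adjusted p = 0.0376). With the block 2 members were higher and 1 lower when adjusted over the list alone. The inhibitory SMAD6 had 0.73 ± 0.25 and the receptor gene BMPR1B -1.18 ± 0.26. Between the same pieces, neuron, glia, red blood cell and leukocyte lists were lower distally (medians -0.97, -0.88, -1.48 and -0.70) and the cartilage list higher (0.31).

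**Figure D1:**
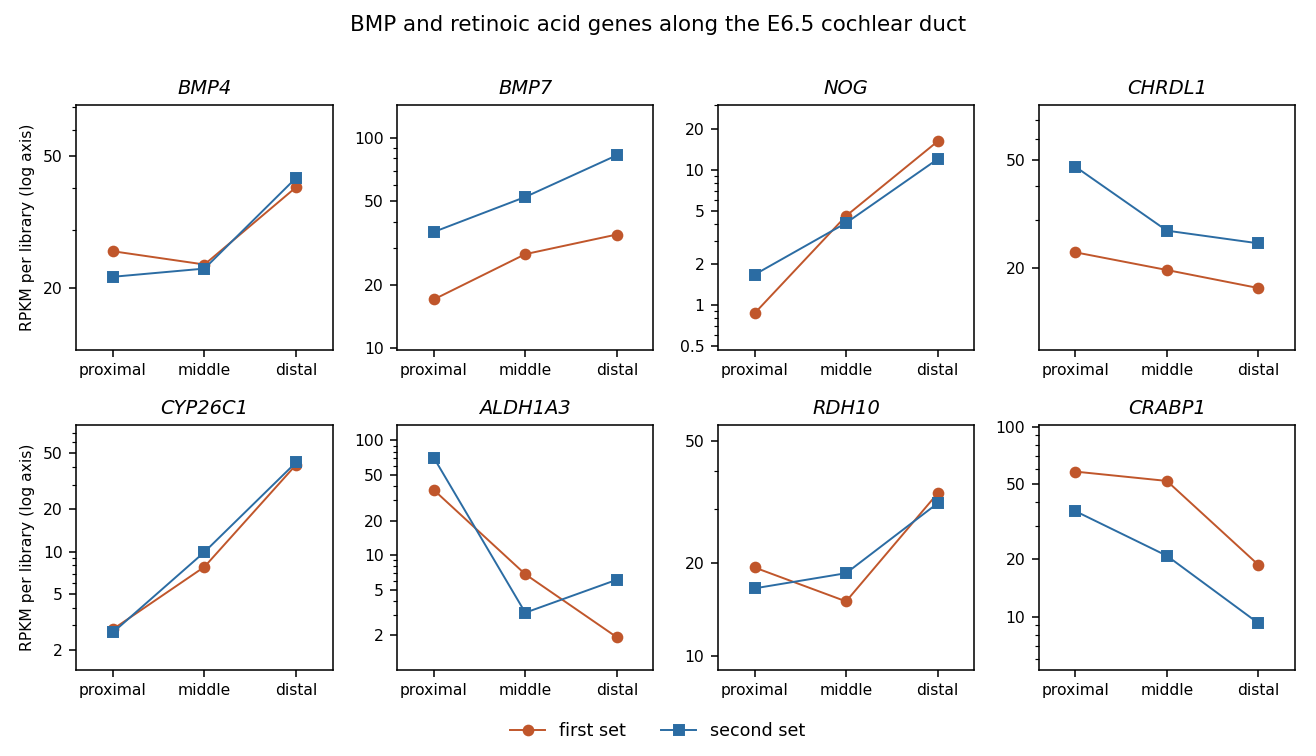
RPKM of 8 BMP and retinoic acid genes (log axis) in the proximal, middle and distal piece, with a point per library and a line per set. CYP26C1, NOG, BMP4, BMP7 and RDH10 were highest in the distal library of each set, while ALDH1A3, CHRDL1 and CRABP1 were highest in the proximal one.

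Retinoic acid genes were on balance lower in the distal piece, where the neuron, glia and red blood cell lists were also lower (medians -0.97, -0.88 and -1.48). Of 14 tested genes 8 were lower and 3 higher in both sets (median -0.61), with camera adjusted p = 0.0157 and adjusted p = 0.312 with an estimated correlation. CYP26C1 was the 1 member that passed over all genes with the block, and 3 were higher and 5 lower when adjusted over the list alone. The members went in different directions for enzymes of the same kind. The synthesis gene RDH10 had 0.82 ± 0.22 and BCMO1, a carotenoid-cleaving enzyme gene, 0.99 ± 0.25, opposite to ALDH1A3, while the breakdown genes CYP26B1 (-1.60 ± 0.27) and CYP26A1 (-0.54 ± 0.21) went opposite to CYP26C1. CRABP1, a retinoic acid binding protein gene, measured 14.0 ± 6.71 against 47.0 ± 15.6 RPKM (-1.72 ± 0.23, blocked limma adjusted p = 0.0534).

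Among the remaining retinoic acid members, the receptor genes RXRG and RARB had changes of -1.41 ± 0.30 and -0.72 ± 0.27, the retinal reductase gene DHRS3 -0.91 ± 0.22 and TGM2 -0.68 ± 0.27. ALDH1A2 (-0.35 ± 0.39), STRA6 (0.17 ± 0.22) and RBP5 (-0.09 ± 0.20) lay within about 1 SE of 0. ALDH1A2 had 0.33 without the second-set proximal library, RBP5 0.76 and 0.60 without the first-set proximal and the second-set distal, and STRA6 -0.003 without the second-set distal. RBP5 had 0.04 under quantile normalization.

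Wnt pathway genes were on balance higher in the distal piece. Of 39 tested genes 26 were higher in both sets and 12 lower in both (median 0.49), with camera adjusted p = 0.0248 and adjusted p = 0.475 with an estimated correlation. WNT5A, WNT4 and LGR5, an R-spondin receptor gene (2.00 ± 0.25), passed over all genes with the block, and 14 were higher and 5 lower when adjusted over the list alone. The receptor gene FZD10 had 2.02 ± 0.28, and WNT2B -2.34 ± 0.38. Cell type lists moved in the same comparison, with neuron, glia, red blood cell and leukocyte markers lower (medians -0.97, -0.88, -1.48 and -0.70) and cartilage genes higher (0.31).

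Other signalling lists were not called. FGFR3, an FGF receptor gene that marks supporting cells, passed with the block (60.8 ± 36.4 against 8.20 ± 6.09 RPKM, 2.79 ± 0.20, limma adjusted p = 0.0163), as the 1 of 27 FGF pathway genes. With the block 4 were higher and 1 lower when adjusted over the list alone. FGF18 and FGFR2 had 1.94 ± 0.30 and 1.67 ± 0.30, and FGF13 -1.56 ± 0.22. The FGF median was -0.02 but the mean 0.24 and the test direction upward (adjusted p = 0.543). In the Notch list, DLK1, a non-canonical ligand gene, passed (1.80 ± 0.22, limma adjusted p = 0.0467) and HES5 had -1.10 ± 0.22, with a list median of -0.11 (camera adjusted p = 0.420 without the block, 2 of 16 higher and 1 lower with the block adjusted over the list alone). Hedgehog genes had a median of 0.04, which turned to -0.06 under quantile normalization, with HHIP at 1.04 ± 0.23 and PTCH1 at 0.87 ± 0.22. Of 13, 2 were higher and 1 lower with the block adjusted over the list alone (camera adjusted p = 0.956 without the block, direction downward). Activin and TGF-beta genes had a median of 0.25 (0 of 12 adjusted over the list alone, adjusted p = 0.240), with TGFB2 at 1.37 ± 0.36.

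Inner ear patterning transcription factors split between the ends. Of 31 tested genes 14 were higher and 15 lower in the distal piece in both sets, and the list was not called (median -0.06, mean -0.28, adjusted p = 0.120). Its median was 0.06 under quantile normalization. GBX2 (2.02 ± 1.53 against 50.2 ± 34.3 RPKM, -4.00 ± 0.27), ZIC1 and EYA2 (-1.80 ± 0.21) passed over all genes with the block, and 7 were higher and 12 lower when adjusted over the list alone. Limma adjusted p with the block was 0.0145 for GBX2 and 0.0442 for EYA2. EMX2 and OTX2 had changes of 1.18 ± 0.18 and 1.11 ± 0.25.

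Prosensory and supporting cell markers were higher in the distal piece and hair cell markers lower, as were neuron, glia, red blood cell and leukocyte markers (medians -0.97, -0.88, -1.48 and -0.70). Of 19 prosensory genes 15 had a mean change above 0 but only 9 were higher in both sets (median 0.24), with camera adjusted p = 0.00339 and adjusted p = 0.470 with an estimated correlation. TECTB and FGFR3 passed over all genes with the block, 6 were higher and 0 lower adjusted over the list alone, and the connexin gene GJB6 had 1.28 ± 0.32. Of 19 hair cell genes 14 were lower in both sets (median -0.62), with camera adjusted p = 5.1e-08 and adjusted p = 0.145 with an estimated correlation. CALB2, which neurons also express, passed over all genes with the block and 9 were lower and 0 higher adjusted over the list alone. Values were -2.51 ± 0.46 for the acetylcholine receptor gene CHRNA10, -2.36 ± 0.35 for ESPNL and -1.44 ± 0.24 for the hair cell transcription factor gene POU4F3. ATOH1, which is required for hair cells, had 0.29 ± 0.32, and -0.32 without the second-set proximal library.

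Macula and otoconia genes were split. The list was called lower in the distal piece (camera adjusted p = 0.0217), but not with the block (0.0990), with adjusted p = 0.312 with an estimated correlation, and of its 10 tested genes 4 were higher and 4 lower in both sets (median -0.16). OTOL1 passed over all genes with the block, and 1 member was higher and 4 lower adjusted over the list alone. NOXO1 and NOX3, which encode parts of the oxidase needed for otoconia, had -1.83 ± 0.24 and -1.49 ± 0.28. OC90, an otoconial protein gene also expressed by the tegmentum, measured 1060 ± 132 against 503 ± 125 RPKM (1.09 ± 0.28). The otopetrin gene OTOP1 had 0.34 ± 0.27, and -0.05 without the second-set distal library. The tegmentum and non-sensory list was not called (median -0.08, mean 0.14, adjusted p = 0.543). Of its 16 tested genes, ATP1B1, which encodes a sodium pump subunit, passed over all genes with the block (-1.60 ± 0.19, limma adjusted p = 0.0442), and 6 were higher and 2 lower adjusted over the list alone. The tight junction gene CLDN8 had 1.26 ± 0.27, and COCH, a cochlin gene, 1.02 ± 0.22.

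Neuron markers were lower in the distal piece. Of 24 tested genes 20 were lower in both sets (median -0.97, -1.12 in the first set and -1.05 in the second), with camera adjusted p = 3.5e-17 and adjusted p = 0.123 with an estimated correlation. NEUROD1, GAP43, NHLH1 and NEUROD4 (-2.19 ± 0.22) passed over all genes with the block, and 16 were lower and 0 higher when adjusted over the list alone. Glia markers followed (median -0.88, 4 of 7 lower in both sets), with camera adjusted p = 0.000195 and adjusted p = 0.312 with an estimated correlation. Of 7 glia genes 0 passed over all genes and 4 were lower with the block when adjusted over the list alone. FOXD3, a neural crest transcription factor gene, and FABP7, which encodes a fatty acid binding protein of glia, had -1.71 ± 0.31 and -1.73 ± 0.26.

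Blood markers were also lower in the distal piece. Red blood cell genes had a median of -1.48 (8 of 8 lower in both sets), with camera adjusted p = 2.4e-08 and adjusted p = 0.392 with an estimated correlation, and 6 were lower adjusted over the list alone with the block. The globin genes HBE, HBZ and HBM had -1.51 ± 0.20, -1.48 ± 0.21 and -1.70 ± 0.32, and reads shared between globin copies make each assignment uncertain. Leukocyte markers had a median of -0.70 (8 of 10 lower in both sets, among them C1QB at -0.90 ± 0.28, camera adjusted p = 0.00099), with adjusted p = 0.470 with an estimated correlation and 0 members adjusted over the list alone. Endothelial markers (median -0.17, SOX18 at -1.02 ± 0.29, adjusted p = 0.156) and melanocyte markers (median -0.39, SLC45A2 at -0.67 ± 0.22, adjusted p = 0.0935) were not called, with 0 members of either adjusted over the list alone.

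Cartilage genes and genes of glycolysis and hypoxia were higher in the distal piece. Of 13 cartilage and otic capsule genes 8 were higher in both sets (median 0.31), with camera adjusted p = 0.0323 and adjusted p = 0.661 with an estimated correlation, and 4 were higher adjusted over the list alone, led by CYTL1 (2.75 ± 0.52). Of 21 glycolysis and hypoxia genes 14 were higher in both sets (median 0.61), with camera adjusted p = 0.00125 and adjusted p = 0.263 with an estimated correlation. LDHA passed over all genes with the block, 8 were higher adjusted over the list alone, and the glucose transporter gene SLC2A1 had 0.99 ± 0.19. Periotic mesenchyme had a median of 0.02 (-0.04 under quantile normalization) and a mean of -0.02, with MEOX2 at -1.70 ± 0.27 and PRRX1 at 1.32 ± 0.26, and was not called (adjusted p = 0.577 without the block, 1 higher and 1 lower of 24 with the block adjusted over the list alone). Muscle genes had a median of 0.58, a mean of 0.09 and a downward test (adjusted p = 0.973 without the block, 5 of 13 higher and 2 lower with the block adjusted over the list alone), with TNNT2 at 1.68 ± 0.29 and the smooth muscle actin gene ACTA2 at -1.68 ± 0.22.

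The last lists were not called either. Ribosomal protein genes had a median of 0.22 (adjusted p = 0.444), S phase and mitosis genes -0.01 (adjusted p = 0.298, with PLK1 at -0.68 ± 0.23), and immediate early and handling stress genes -0.47 (adjusted p = 0.155, with JUN at -0.58 ± 0.22). In each of these 3 lists 0 members passed adjusted over the list alone. Axon guidance genes had a median of 0.03 (-0.08 under quantile normalization), a mean of -0.07 and a downward test (adjusted p = 0.358 without the block), with NTN1, which encodes netrin, at -1.50 ± 0.21, and 3 higher and 5 lower of 29 with the block adjusted over the list alone. In all, camera called 12 lists without the block (5 higher, 7 lower in the distal piece) and 10 with it, of which 0 held with an estimated correlation in either model. Without the second-set proximal library 6 were called, all lower. With the block that library's omission left 5.

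**Figure D2:**
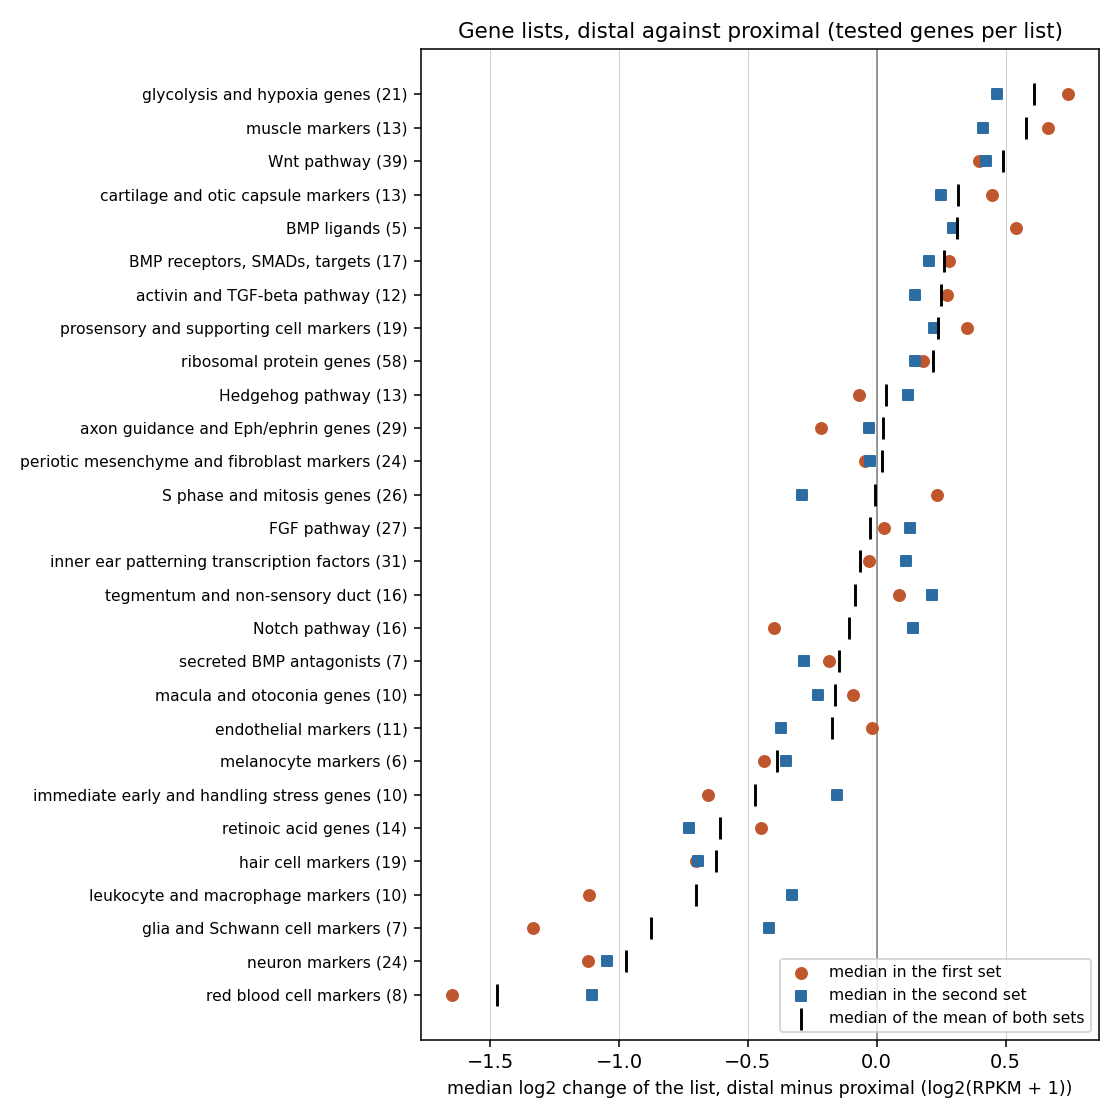
Median log2 change of each of 28 gene lists between the distal and the proximal piece, on the log2(RPKM + 1) scale, in the first set (circles), the second set (squares) and for the mean of both (bars). Red blood cell (median -1.48), neuron (-0.97) and glia (-0.88) markers lie lowest, and glycolysis and hypoxia genes (0.61) highest. The medians of the Hedgehog, patterning, mesenchyme and guidance lists change sign under quantile normalization.

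The middle piece was next compared with the proximal piece. APOA1 measured 50.3 ± 24.4 RPKM in the middle and 3.17 ± 0.401 in the proximal piece (3.54 ± 0.27), TECTB 12.1 ± 1.85 against 1.28 ± 0.530 (2.54 ± 0.33) and FGFR3 42.7 ± 25.0 against 8.20 ± 6.09 (2.30 ± 0.20). Macular and hair cell genes stood lower, with OTOP1 at 3.96 ± 0.255 against 42.9 ± 10.02 (-3.13 ± 0.27), OTOL1 at 2.94 ± 1.57 against 33.3 ± 14.0 (-3.12 ± 0.25) and CALB2 at 11.7 ± 4.93 against 116 ± 79.3 (-3.06 ± 0.31). No gene passed the threshold. Limma called 0 genes without the block (111 at an unadjusted p under 0.05) and 0 with it (484), where the smallest adjusted p was 0.0780. Further genes by the rule were CYP26C1 (1.39 ± 0.22), CBLN4, which encodes a synapse organizer of the cerebellin family (1.16 ± 0.19), and the transcription factor gene SOX14 (1.26 ± 0.23) on the higher side. On the lower side they were OCM2 (-3.26 ± 0.25), HMX3, a vestibular homeobox gene (-2.25 ± 0.24), and ALDH1A3 (-3.20 ± 0.53). At least 2-fold in both sets, 28 genes were higher and 56 lower in the middle piece, against 4.71 and 4.34 for independent sets, and 8 went opposite ways, but over all genes only 35.4% had the same sign in both sets. With 1 library left out the blocked count was 49 without the first-set proximal, 5558 without the second-set proximal, 22 and 83 without the first-set and second-set middle, and 84 and 85 without the first-set and second-set distal.

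Hair cell markers fell from the proximal to the middle piece. Of 19 genes 13 were lower in both sets (median -0.55), with camera adjusted p = 1.3e-20 and adjusted p = 0.0679 with an estimated correlation. Macula and otoconia genes (median -0.56, adjusted p = 2.5e-09, 0.0992 with an estimated correlation), retinoic acid genes (median -0.44, adjusted p = 1.9e-05, 0.149 with an estimated correlation) and periotic mesenchyme (median -0.13, adjusted p = 0.00125, 0.500 with an estimated correlation) were lower too. Adjusted over the list alone with the block, 9 hair cell, 5 macula, 3 retinoic acid and 0 mesenchyme genes were lower, and 1 retinoic acid gene was higher. Red blood cell (median -1.11, adjusted p = 8.4e-11, 0.451 with an estimated correlation), leukocyte (median -0.50, adjusted p = 1.6e-06, 0.451 with an estimated correlation) and glia markers (median -0.22, adjusted p = 0.0303, 0.500 with an estimated correlation) were called lower as well. The glia median was -0.31 in the first set and 0.01 in the second, with 2 of 7 genes lower in both. Patterning factors were called lower at a median of 0.03 and a mean of -0.26 (adjusted p = 0.00735, 0.676 with an estimated correlation). Prosensory markers were higher (median 0.36, adjusted p = 0.00125, 0.500 with an estimated correlation). The block added the endothelial list (median -0.18, adjusted p = 0.0490, 0.416 with an estimated correlation). Without the second-set proximal library the block called 4 lists where it had called 10. Neuron markers were not called (median 0.09, adjusted p = 0.807), nor were the remaining lists (smallest adjusted p = 0.0650 without the block).

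Between the distal and the middle piece no gene passed the threshold, and the genes named by the rule had OTOP1 and MSX1 higher and GAP43 and CHGA lower in the distal piece. OTOP1 measured 55.9 ± 21.2 RPKM in the distal and 3.96 ± 0.255 in the middle piece (3.47 ± 0.27), MSX1 95.3 ± 6.36 against 6.73 ± 0.601 (3.64 ± 0.38), FGF8 12.4 ± 0.0716 against 1.09 ± 0.409 (2.69 ± 0.24) and ATOH1 35.9 ± 6.76 against 7.86 ± 0.131 (2.05 ± 0.32). WNT4 and CYP26C1 had changes of 2.11 ± 0.20 and 2.14 ± 0.22. GAP43 measured 47.8 ± 5.38 against 237 ± 59.3 (-2.27 ± 0.23), CHGA had -2.16 ± 0.26, NRN1 -1.88 ± 0.27, EYA2 -1.78 ± 0.21, STMN4, a neuronal stathmin gene, -1.74 ± 0.22, and VSTM2A, which encodes a secreted immunoglobulin-domain protein, -1.73 ± 0.21. Limma called 0 genes without the block (210 at an unadjusted p under 0.05) and 0 with it (960), and blocked adjusted p for these 12 lay between 0.156 and 0.178. At least 2-fold in both sets, 53 genes were higher and 155 lower in the distal piece, against 1.54 and 8.62 for independent sets, and 5 went opposite ways. Over all genes 70.6% had the same sign in both sets. Array weights with the block called 1738 genes. With 1 library left out the blocked count was 1257 and 1113 without the first-set and second-set proximal, 38 without either middle library, and 13 and 71 without the first-set and second-set distal.

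**Figure D3:**
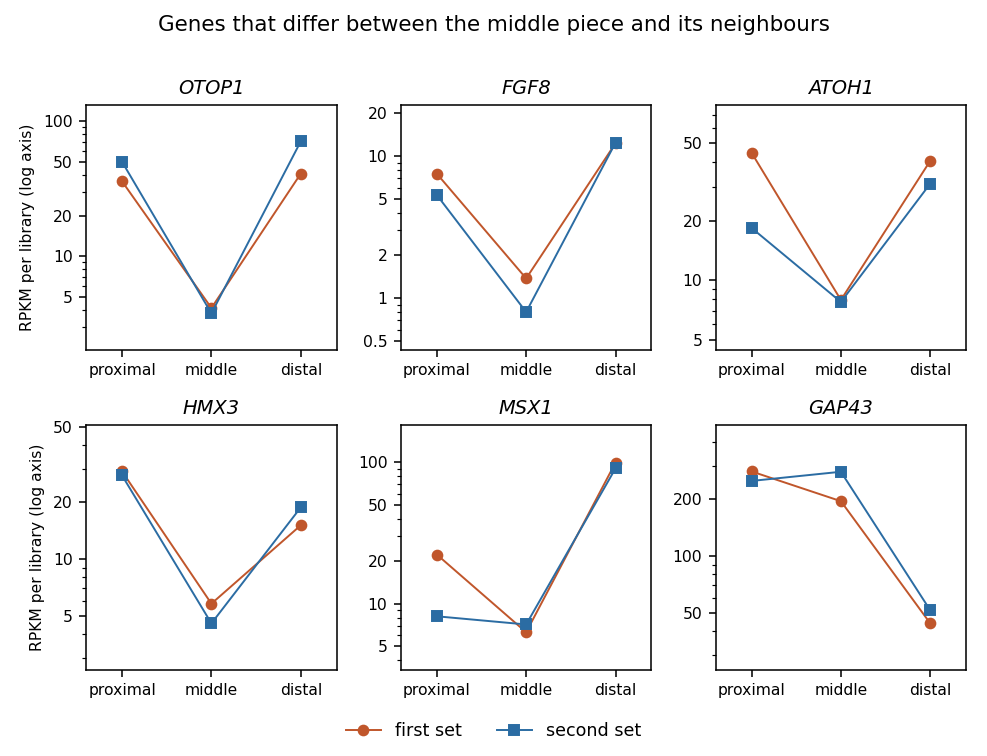
RPKM of 6 genes (log axis) named between the middle piece and its neighbours, with a point per library and a line per set. OTOP1, FGF8, ATOH1 and HMX3 were lowest in the middle library of each set, and GAP43 lowest and MSX1 highest in the distal library of each set.

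Neuron markers fell from the middle to the distal piece. Of 24 genes 23 were lower in both sets (median -1.21), with camera adjusted p = 3.7e-37 and adjusted p = 0.0394 with an estimated correlation, though 0.368 with an estimated correlation and the block. With the block 21 were lower adjusted over the list alone and 0 over all genes. Glia markers (median -0.76, adjusted p = 0.000219, 0.519 with an estimated correlation) and red blood cell markers (median -0.34, adjusted p = 0.0313, 0.637 with an estimated correlation) were lower. Higher in the distal piece were the Wnt list (median 0.23, adjusted p = 4.6e-05, 0.535 with an estimated correlation), glycolysis and hypoxia genes (median 0.29, adjusted p = 7.4e-06, 0.166 with an estimated correlation), cartilage genes (median 0.39, adjusted p = 4.5e-05, 0.637 with an estimated correlation) and FGF genes (median 0.18, adjusted p = 0.0404, 0.637 with an estimated correlation). Adjusted over the list alone with the block, 4 Wnt, 5 glycolysis, 4 cartilage and 3 FGF genes were higher, and 2 glia genes and 1 FGF gene lower. The block added activin and TGF-beta (median 0.24, adjusted p = 0.0398), mesenchyme (median 0.16, adjusted p = 0.0410) and ribosomal protein genes (median 0.15, adjusted p = 0.0191), with adjusted p = 0.595, 0.550 and 0.550 with an estimated correlation. The remaining lists were not called. Without the block camera called 7 lists, against 16 without the second-set middle library and 13 without the first-set distal.

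Across all 3 regions, OTOP1, OTOL1, OCM2, GBX2, APOA1, CYP26C1 and FGFR3 differed with the block in the moderated F test, along with 2 genes without a symbol. Adjusted p in limma was 0.0428 for OTOP1 and 0.0370 for the others. OTOP1 had low values in the middle piece alone, whereas the other named genes had middle values between the ends. Without the block limma called 0 genes (297 at an unadjusted p under 0.05). The blocked count was 0 with a pseudocount of 0.1 or with no filter on low values, and 65 under quantile normalization. It ranged from 157 (without the first-set distal library) to 6542 (without the second-set proximal) when 1 library was left out, with 1106 without the first-set proximal, 451 and 469 without the first-set and second-set middle, and 314 without the second-set distal.

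The position of the middle piece was taken for the 66 genes called between the ends with the block. The middle mean lay between the end means for 63 of them and beyond the proximal mean for 3. The median position was 0.45 of the way from proximal to distal on the log2 scale, with 33 genes nearer the proximal and 30 nearer the distal value. In 100 simulations in which no region differed, a mean of 55.8 of the 66 genes with the smallest p between the ends had their middle mean between the end means, at a median of 0.50. CYP26C1 and NEUROD1 were nearer to the proximal level (8.88 ± 1.52 and 27.7 ± 3.99 RPKM in the middle piece), and OTOL1, CALB2 and FGFR3 nearer to the distal level.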

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

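The combinations of the replicate block with another choice, the array weights, the position of the middle piece with the block and the comparison of the middle with both ends were chosen only after the data were seen, and the other alternatives before. Of 1418 recomputed log2 changes of named genes (143 gene and comparison pairs), 1366 kept their direction and side of the threshold, 39 passed the threshold where they had not (37 of them with the block), and 13 changed sign, in 8 genes. As the unblocked model called 0 genes, keeping the side of the threshold meant staying uncalled. Genes named for libraries that did not overlap between the regions could not change sign when 1 library was left out. Of 166 recomputed counts, 110 stayed within 1.5 times the unblocked count and 56 moved, and many of those that stayed were 0 in both fits. Where 1 library is left out, the lone library of its region is assumed to vary like the others.

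The number of genes changed between distal and proximal was 0 unblocked, 3 when only these 2 regions were fitted, and 66 with the block, since the block removes the difference between the sets from the spread. With the block it was 36 with a pseudocount of 0.1, 40 with a mean RPKM of at least 5, 257 under quantile normalization, 64 with no trend and 40 with array weights, and it shared 36, 40, 66, 61 and 37 genes with the 66. The block with no filter on low values gave 0. The number for any region was 0 unblocked and, with the block, 9, and 9, 65, 6 and 1181 with a mean RPKM of at least 5, quantile normalization, no trend and array weights. Between middle and proximal the block gave 3 under quantile normalization and 1 with array weights, and between distal and middle 1738 with array weights, against 0 otherwise. Beyond the block, the cause was not tested. The block changed no other call apart from those given for the BMP target, macula, endothelial, activin, mesenchyme and ribosomal protein lists, and for the neuron list between distal and middle with an estimated correlation (0.0394 unblocked, 0.368 with the block).

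Leaving out 1 library, with and without the block, gave 0 to 6962 genes between distal and proximal, 0 to 5558 between middle and proximal, 0 to 1257 between distal and middle and 0 to 6542 for any region. The extremes of the first, second and last of these came with the block and without the second-set proximal library, where 1 residual degree of freedom fewer is left, and the cause was not tested. Between distal and proximal these blocked fits shared most of the 66 genes, but this is not independent support. They used mostly the same libraries, and each called more genes than the 66.

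With an estimated correlation, camera called 0, 0 and 1 lists for distal against proximal, middle against proximal and distal against middle, and with the block 0, 0 and 0, where 12, 9 and 7 were called at the preset one. Without the block, between distal and proximal, the estimated correlation lay below the preset for retinoic acid (-0.061), macula (-0.026) and glycolysis genes (-0.040). Their unadjusted camera p still rose, from 0.0045, 0.0070 and 0.00027 to 0.057, 0.067 and 0.028. That of hair cell markers (0.0115) rose from 5.4e-09 to 0.0103. For these lists a higher correlation is argued against as the cause. The estimate was above the preset in the other called lists, and the cause was not tested further. Leaving out 1 library gave 5 to 14, 4 to 13 and 5 to 16 lists, and the cause was not tested. Among the genes called between the ends, the middle lay between for 63 with the block. Unblocked, with 1 library left out, it did so for 0 to 1, as those fits called 0 or 1 genes.

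The sign changed for genes whose change was small. Under quantile normalization TWSG1 had 0.0447 and RBP5 0.0440. With 1 library left out the changes ranged from -0.19 to 0.82 for BMP2, -0.60 to 0.30 for SOSTDC1, -0.30 to 0.26 for TWSG1, -1.02 to 0.33 for ALDH1A2, -0.0031 to 0.34 for STRA6, -0.94 to 0.76 for RBP5, -0.0498 to 0.73 for OTOP1 and -0.32 to 0.91 for ATOH1, and the cause was not tested. Depth limits the low genes of the first-set distal library most, where 1 read per kilobase is worth 0.108 RPKM.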

Other observations

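The comparison of the middle piece with the mean of both ends, the genes in this and the next paragraph, and all tests below were chosen after the results were seen. Some genes had middle values below those of both ends, though none passed the threshold. OTOP1 differed from the mean of the ends by -3.30 ± 0.23, FGF8, which encodes a signalling ligand, by -2.26 ± 0.21, and the homeobox genes HMX3 and MSX1 by -1.89 ± 0.20 and -2.28 ± 0.33. The MSX1 value came mainly from the distal end. Its middle level was 6.30 and 7.15 RPKM in the first and second set, against 22.3 and 8.17 proximally and 99.8 and 90.8 distally. The hair cell transcription factor genes ATOH1, GFI1 and LHX3 had -1.90 ± 0.28, -1.38 ± 0.20 and -1.33 ± 0.21. In the other direction the neuronal stathmin gene STMN2 had 1.18 ± 0.24 and VSTM2A 1.24 ± 0.18. By at least 1 log2 unit in size, 15 genes were lower and 12 higher in both middle libraries than in all 4 end libraries. Limma called 0 genes with or without the block (424 at an unadjusted p under 0.05 with it), and OTOP1 had blocked adjusted p = 0.126. Camera gave adjusted p = 2.3e-10 for hair cell markers (median -0.54) and 1.3e-05 for macula and otoconia genes (median -0.22). It gave 3.2e-26 for neuron markers (median 0.72), and each of the 3 had 0.325 with an estimated correlation. Hair cell markers had a median of -0.06 in the distal minus the middle piece, and neuron markers 0.09 in the middle minus the proximal piece. The middle piece thus differed mainly from 1 end in these markers. Other cell types were called lower in the middle piece too, among them mesenchyme (median -0.21, adjusted p = 1.3e-05), cartilage (-0.23, 1.3e-05), red blood cell (-0.36, 0.000363) and leukocyte markers (-0.23, 0.00117), each with 0.326 with an estimated correlation. So were glycolysis and hypoxia (-0.17, 0.000202), retinoic acid (-0.18, 0.000728), Wnt (-0.06, 0.000909) and Hedgehog genes (-0.16, 0.00110). BMP antagonists (-0.15, 0.0328) and activin and TGF-beta genes (-0.18, 0.0331) were called lower as well. With an estimated correlation, camera adjusted p of these lists lay between 0.325 and 0.530. Neuron markers were the only list called higher.

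Several genes outside the naming rule passed between the ends with the block. Higher in the distal piece were RGR, an opsin family gene (2.91 ± 0.23), ADAMTS1, which encodes a matrix protease (2.17 ± 0.19), IGFBP5, which encodes a binding protein of insulin-like growth factors (1.96 ± 0.19), and the serotonin receptor gene HTR1A (2.11 ± 0.25). Lower were VIP, a neuropeptide gene (-2.50 ± 0.28), and the endothelin receptor gene EDNRB of neural crest cells (-2.14 ± 0.21). Blocked limma adjusted p lay between 0.0268 and 0.0442.

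Neuron markers were lower in the distal piece (median -0.97). A scaling of the RPKM values is argued against, since the median was -0.97 after quantile normalization too. The first-set proximal library alone is argued against by the second set, with a median of -1.05 (-1.12 in the first set). A lower share of ganglion cells in the distal piece goes with the glia medians of -1.33 in the first set and -0.42 in the second, as glia lie in the same ganglion. A drop of both may reflect how much ganglion each piece kept. Red blood cell and leukocyte lists were lower in the distal piece too (medians -1.48 and -0.70), so the glia drop does not single out the ganglion. Lower expression per neuron, and a real difference in the ganglion along the duct, were not tested and stay open.

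Hair cell and macula genes were lower in the middle piece than the mean of both ends, but between the distal and the middle piece neither list was called (adjusted p = 0.413 and 0.407), and mesenchyme, cartilage, red blood cell and leukocyte lists were also lower than the mean of the ends (medians -0.21, -0.23, -0.36 and -0.23), all 6 calls being lost with an estimated correlation (0.325 or 0.326). Scaling is argued against, since the median difference of both lists from the mean of the ends was -0.34 after quantile normalization and -0.31 before. If the ends each held the same macular tissue, the genes at least 1 log2 unit lower in the middle than in the proximal piece in both sets would be higher again distally. Of the 29 listed genes tested 9 met this. Of these, 55.6% were higher again in the distal piece in both sets (5 of 9, ATOH1, GFI1, LHX3, OTOP1 and SLC17A8), while ESPNL, OTOL1 and POU4F3 were lower still in both sets. Some of these differences were small, with SLC17A8 at 0.15 and 0.33 and POU4F3 at -0.31 and -0.02 in the first and second set. Both comparisons used the same middle libraries, so a middle value that was low by noise would count toward both. Whether macular tissue at both ends explains the first group cannot be told apart from other sources, as so few genes and single pools per set decide little, and proximal and distal maculae need not share all genes.

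The sets differed more than the regions. Depth alone is argued against, since ribosomal protein genes, which are far above the reading floor, differed between the sets by medians of -1.23 in the proximal, -1.40 in the middle and -1.35 in the distal piece (second minus first), opposite in sign to the all-gene medians of 0.46, 0.24 and 0.22. The library kit and the embryos of each set cannot be told apart as sources of the first principal component (63.4% of the variance), because the kit of each library, and how embryos were shared between the libraries of a set, are not given in the sources used here. No biological explanation was tested for this pattern.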
